A study of Drosophila melanogaster with 33 samples.

How the data were processed

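The measurements came from ovarian somatic cells (OSC), a Drosophila melanogaster line of ovarian follicle-cell origin that lacks germ cells and in which Piwi is the only PIWI protein at work. Piwi is a nuclear Argonaute protein that carries piRNAs, small RNAs that direct the silencing of transposable elements (TEs). In CLASH, a target RNA is ligated to the piRNA that pairs with it inside the purified protein, and the joined molecule is sequenced as a chimera. CAGE counts the capped 5' ends of RNAs, and Iso-seq reads full-length cDNA on a PacBio instrument. Of the 33 samples in the series, 5 were CLASH libraries from untreated cells. A further 12 were CAGE entries, 6 from cells treated with siRNA against EGFP (the control, EGFP KD) and 6 from cells treated with siRNA against piwi (Piwi KD). Iso-seq had 2 EGFP KD and 2 Piwi KD samples, small RNA sequencing had 3 samples, and genomic DNA had 1. The 8 ChIP samples were not analysed here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

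Reads were processed before deposit with cutadapt 4.0, HISAT2 2.2.1, Bowtie 1.0.0, Bowtie2 2.2.5, STAR 2.7.10b, bedtools 2.30.0, minimap2, SAMtools and deepTools against the dm6 build, per the submitters' processing notes, which name no role for any tool. All genomic coordinates are dm6 and counted from 1. The deposited CAGE table held whole-number counts of tags per tag cluster and library, with a gene name for each cluster, per the file headers. Its columns carry 1 library per replicate where the labels list 2 entries, and whether those were summed was not given in the sources used here, so n was 3 per group. The deposited Iso-seq tables held counts of full-length reads per isoform and library, per the file headers. Their columns name 1 library per condition without a number and 1 with the number 2. The deposited small RNA table gave CPM per sequence, per the file name, and listed values below about 1 as 0. The listed values sum to between 184158 and 234406 per library, so the authors' denominator held other reads. The authors' CLASH tables gave, for each chimera, the piRNA, the target class, the target region and a hybridization free energy. Refolding each pair with RNAduplex (ViennaRNA 2.7.2) at 26 °C returned the deposited energy within 0.05 kcal/mol for 97.2% of chimeras. The deposited TE annotations of the assembled flam and 20A piRNA clusters carry a score that runs like a percent divergence from the TE consensus, although the file has no header. The deposited tag cluster lists for each knockdown hold positions alone. Left unused were 4 value columns of the small RNA table (3 of single libraries and 1 mean) and 3 CLASH libraries, since no sample of the series carries their names.

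CAGE clusters were summed to genes. The 7640 clusters named 6149 genes, of which 6131 identifiers matched the gene name table. Genes sharing a cluster were kept as 158 joint features, which left 6022 features. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, the quasi-likelihood test), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. DESeq2 1.42.0 was an alternative. The table held 0 transposon rows, so the planned test of TE families in CAGE was not possible and TE families were taken from Iso-seq. Iso-seq isoforms were summed to 9378 features (genes, joint genes, unannotated loci and TE families), of which 4409 passed the filter, and tested in the same way. Pooled Iso-seq folds carry an exact binomial 95% interval, and shares carry a Wilson 95% interval. Both cover counting error only, since the reads are not independent molecules. A fold against 0 reads was computed against a floor of 3 reads over the group and is a lower bound.

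Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation. The 18 lists tested covered the somatic piRNA pathway, the germline piRNA pathway, germ cells, follicle cells, hemocytes, neurons, muscle, heterochromatin, siRNA and miRNA machinery, heat shock proteins, innate immunity, JAK-STAT and JNK, DNA damage and apoptosis, the cell cycle, Hippo, ecdysone, Notch, and ribosomal proteins. A further pair of lists split TE families into those known from follicle cells and those known mainly from the germline. A set's median was also placed among the medians of 10000 random lists matched on mean expression. CLASH measures were summarised per library as medians or shares of distinct chimeras, and TE and mRNA targets were compared within each library by an exact two-sided sign-flip permutation test. With 5 libraries the smallest p that test can give is 0.0625, so it cannot reach 0.05. As a background, piRNAs and targets of one class and library were re-paired at random 3 times and refolded. Correlations across TE families used 100000 permutations. Tag clusters of the knockdowns were compared with bedtools 2.31.1 on the same strand, with a shared cluster overlapping by at least 1 bp. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

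The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took piwi; up to 4 changed members of each list by smallest adjusted p; and the 10 largest rises and 10 largest falls among changed genes with a mean count of at least 20 and no overlap between groups. It also took the 10 TE families and 10 genes with most chimeras that occur in each CLASH library, the most abundant piRNA sequences, and the 5 Iso-seq features with the smallest p each way. Genes named outside it are said to be so. The alternatives covered the scaling, the test, the count filter, the replicate number as a block, a minimum fold, clusters in place of genes, read weights and read minimums for chimeras, and each replicate left out in turn. Added after the data were seen were library totals without scaling, the Iso-seq library set as a term, CLASH libraries in 2 sets, piRNAs of the flam type alone, targets of 40 to 50 nt, the use of Iso-seq changes and flam bases in the relation across TE families, and the sets of genes fused to a TE.

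Numbers in the CAGE labels paired the libraries in part. After group means were removed, EGFP KD and Piwi KD libraries of the same number correlated at 0.48, 0.12 and 0.31 across genes for numbers 1, 2 and 3. Libraries of different numbers correlated at -0.41 to 0.23. The highest of these, EGFP KD 2 with Piwi KD 3, lay above the value for number 2. Replicates within each CAGE group differed by more than sampling noise, with a chi-square per degree of freedom between 3.45 and 16.5. The CAGE fit was tested on simulated counts of 6021 genes with a known set of changed genes. It recovered 86.6%, 100% and 98.5% of genes changed 1.5-, 2- and 4-fold, and 13 of its 203 calls were on unchanged genes. The simulation changed 67, 67 and 66 genes by these folds, up and down in balance, and built in no pairing of replicates. With 1974 genes called in the real data, it does not probe the scaling or the error rate at that number. The same test of the Iso-seq fit on 4439 features recovered 0% at each of these folds. With the library set as a term it recovered 7.46%, 40.3% and 80.3%, and 1 of 86 calls was on an unchanged feature.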

Results

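The series profiled ovarian somatic cells, a follicle-cell line of the Drosophila ovary, with and without knockdown of piwi, and asked by its title whether transposons and mRNAs are told apart by how piRNAs pair with them and how abundant those piRNAs are. CAGE counted capped 5' ends in 3 EGFP KD and 3 Piwi KD libraries. The EGFP KD libraries held 10833703, 11846343 and 10548844 counts for replicates 1, 2 and 3, and the Piwi KD libraries held 10482920, 10482516 and 9412070. Iso-seq gave 323327 and 233057 full-length reads in the EGFP KD libraries without a number and numbered 2, and 339391 and 195783 reads in the matching Piwi KD libraries. CLASH of Piwi in untreated cells gave 9120, 4186, 2722, 1673 and 2916 distinct chimeras in libraries 1 to 5. The small RNA table listed sequences of 23 to 30 nt, 135957 of them above 0 in at least 1 of the 3 libraries, and the assembled genome contributed annotated haplotypes of the piRNA clusters flam and 20A.

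The target of the knockdown, piwi, was lower in each Piwi KD library. Its CAGE level was 696 ± 28.2 CPM in EGFP KD and 150 ± 7.34 CPM in Piwi KD (SD, n = 3 each, TMM-scaled), a log2 fold change of -2.22 (SE 0.06, edgeR adjusted p = 7.03e-10). Its tags fell in 1 cluster at chromosome 2L, 10987335 to 10987446, on the minus strand. In Iso-seq, piwi had 902 and 167 reads in the EGFP KD libraries and 61 and 6 in the Piwi KD libraries.

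Piwi knockdown was accompanied by changes in many genes, most of them small. The largest rises reached over 20-fold and included Irk1, an inwardly rectifying potassium channel, and Oat, the ornithine aminotransferase. Among the largest falls were the serine protease gene flz, the cytochrome P450 gene Cyp6d5 and ImpL2, which encodes a secreted insulin-binding protein. Of 6021 genes tested with edgeR's quasi-likelihood test, 1974 had an adjusted p under 0.05, 877 higher and 1097 lower in Piwi KD. The groups did not overlap for 46.8% of genes, where chance gives 10% if the 6 libraries are exchangeable. The partial pairing by replicate number puts that condition in doubt. At least a 2-fold change was seen for 232 of the changed genes, 81 higher and 151 lower. With the replicate number as a block the higher genes came to 1344. The balance of directions depended on the scaling. With library totals in place of TMM factors, an alternative added after the data were seen, 2619 genes were higher and 566 lower, and the median of all genes moved from 0.01 to 0.193 on the log2 scale. Without Piwi KD replicate 2 the count of changed genes was 1306.

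Oat went from 9.58 ± 1.51 CPM in EGFP KD to 232 ± 22.6 CPM in Piwi KD (SD, n = 3 each), with a log2 fold change of 4.60 (SE 0.11, edgeR adjusted p = 5.54e-10). Its tags lay at chromosome 3L, 19649831 to 19649849, on the minus strand. CG15209 rose by 3.65 on the log2 scale, from 10.6 to 134 CPM, at chromosome X, 10842198 to 10842232. CG42565 and the cadherin gene CadN2 rose by 4.33 and 3.41. Irk1, CG8303 and the serine protease gene Sp7 rose by 5.08, 4.22 and 3.85, and mlt, CG11459 and the cytochrome P450 gene Cyp6a9 rose by 4.47, 4.16 and 4.07. Irk1, mlt, CG11459, Cyp6a9 and Sp7 averaged under 1 CPM in EGFP KD, so their fold changes rest on few control tags. Cyp6d5 went from 224 ± 25.3 to 22.02 ± 2.17 CPM, a log2 fold change of -3.35 (SE 0.10, edgeR adjusted p = 1.53e-09), at chromosome 3R, 14029226 to 14029239, on the plus strand. ImpL2 went from 60.0 ± 9.97 to 7.29 ± 1.29 CPM. The steepest falls were those of CG17104 at -4.88, flz at -4.36 and Amnionless at -4.03. Prm, which encodes paramyosin, fell by 3.58, and dpr17 and olf413 each fell by 3.51. The log2 fold changes of Exn and T48 were -3.18 and -3.17.

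**Figure D1:**
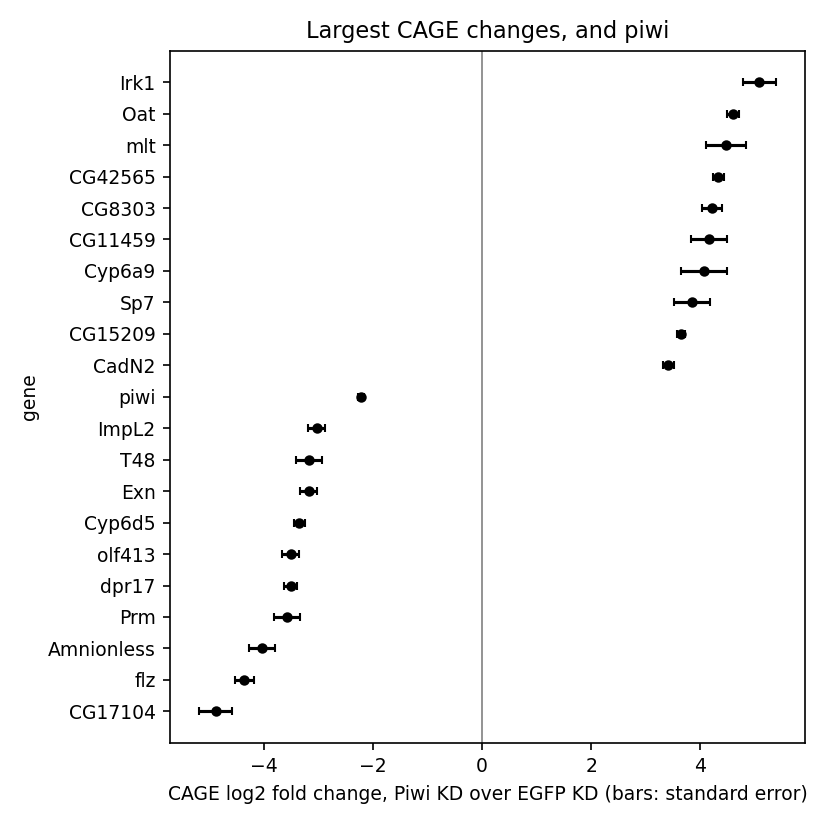
CAGE log2 fold change (Piwi KD over EGFP KD, horizontal axis) of the 10 largest rises, piwi and the 10 largest falls, with bars of 1 standard error and 3 libraries per group. Irk1 lies highest at 5.08, CG17104 lowest at -4.88 and piwi at -2.22.

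Ribosomal protein genes moved together. Of 81 measured, 68 were lower in Piwi KD and 1 was higher, with a median log2 fold change of -0.35. Their share of all CAGE counts was 33.1 ± 0.537% in EGFP KD and 29.7 ± 0.551% in Piwi KD (SD, n = 3 each). RpL29 went from 1325 to 875 CPM and RpL3 from 3407 to 2350 CPM, and RpL18 had a log2 fold change of -0.46. This was the only one of the 18 lists past the threshold in camera (adjusted p = 1.96e-17), and the adjusted p was 0.333 with an estimated correlation. Adjusted over the list alone, 77 members were lower and 1 higher. The median was -0.36 with RLE or DESeq2 size factors and -0.17 with library totals.

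None of the lists below passed the adjusted threshold in camera. Their counts are to be read beside 877 higher and 1097 lower of all 6021 genes tested. The Notch pathway list had 6 members higher and 1 lower of 13 measured (camera p = 0.0376, adjusted p = 0.172, and p = 0.291 with an estimated correlation). E(spl)malpha-BFM, a Notch target of the Bearded family, went from 27.1 ± 3.86 to 89.6 ± 11.1 CPM. The glycosyltransferase gene fng rose by 1.22 on the log2 scale, E(spl)mbeta-HLH rose by 0.84, and mam, a Notch coactivator, fell by 0.68. In the somatic piRNA pathway, 5 of 25 genes were higher and 4 lower, piwi among the latter. The cofactor gene wde, whose product acts with the H3K9 methyltransferase Eggless, rose by 1.31 from 3.48 ± 1.25 CPM, daed rose by 0.37, and shu had a log2 fold change of -0.48. Of 7 germline piRNA genes measured, spn-E and squ rose by 0.46 and 0.64, and del, which encodes a partner of Rhino, fell by 0.56. Of 18 heterochromatin genes, wde, HP5 and Su(var)2-10 were higher, the last by 0.16, and Kdm4B was lower at -0.57. Heat shock protein genes were higher in 5 and lower in 1 of 12. Hsp67Ba and Hsp23 rose by 1.10 and 0.83, and the co-chaperone gene stv fell by 0.66.

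Among markers of other cell types, 1 muscle gene fell and 1 rose of 2 measured. The actin gene Act57B went from 133 ± 11.5 to 21.7 ± 0.983 CPM, and Mef2 rose by 0.42. The neuronal microtubule gene futsch, the single neuron marker measured, had a log2 fold change of -1.90, and the 1 hemocyte marker measured did not pass the test. Germ cell markers were higher in 2 of 6 (stau by 0.45 and CycB3 by 0.25) and lower in 0. The follicle and somatic gonad markers split, with 3 of 10 higher and 3 lower. Among them, the homeodomain gene ct rose by 1.67, the eggshell gene dec-1 rose by 2.10, and hh had a log2 fold change of -0.59.

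The JAK-STAT and JNK list had 1 higher and 2 lower of 12. The matrix metalloproteinase gene Mmp1 went from 30.99 ± 4.17 to 95.9 ± 10.2 CPM, and chinmo and hep had log2 fold changes of -0.61 and -0.41. In the Hippo list, fj and dally were lower at -0.84 and -1.38 and sd rose by 0.77, with 1 higher and 3 lower of 12. The ecdysone list had 1 higher and 3 lower of 8, ImpL2 and Hr39 (-0.60) among the lower. In the cell cycle list, 4 of 32 were higher and 3 lower. The Cdc25 phosphatase gene stg fell by 0.82 and Mcm7 rose by 0.51. The DNA damage and apoptosis list had 1 higher, Corp at 1.49, and 4 lower of 19, RnrS and Dcp-1 among them at -0.28 and -0.25. The siRNA and miRNA list had 4 higher and 1 lower of 9, with Dcr-1 at 0.32 and Dcr-2 at -0.30. Of 4 immunity genes measured, pirk rose by 0.87 and cact fell by 0.28. Adjusted over the list alone, the counts of these 17 lists other than ribosomal proteins differed in 3. These were heterochromatin with 2 higher, DNA damage with 2 lower and the cell cycle with 3 higher. The medians of the immunity (-0.13), DNA damage (-0.07), Hippo (-0.01) and ecdysone (-0.05) lists were above 0 with library totals in place of TMM factors. The calls of stau, CycB3, Mef2, Su(var)2-10, squ, Dcr-1, Dcp-1 and cact were each lost in 1 or more of the 6 fits that left out a library, and those of Dcp-1, Dcr-2, RnrS and cact with library totals. The mean had another sign than the median for immunity (0.07) and for the somatic piRNA pathway (-0.02).

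Iso-seq was used to ask which TE families had more transcripts when Piwi was depleted. Full-length TE reads made up 3.06% (95% Wilson interval 3.002 to 3.121) and 2.85% (2.78 to 2.92) of reads in the EGFP KD libraries without a number and numbered 2. In the matching Piwi KD libraries they made up 6.46% (6.37 to 6.54) and 6.60% (6.49 to 6.71). Most families with the largest folds were LTR retrotransposons known from follicle cells. Of 16 such families tested, 14 were higher in both Piwi KD libraries than in both EGFP KD libraries and 0 were lower, where chance separates the groups either way in 33.3% of features if the 4 libraries are exchangeable. They fell into 2 sets by their numbers, which makes that rarer, and 10.7% of the 4179 genes tested were separated either way. The median log2 fold change of these 16 was 5.75. Reads of 297 went from 6 and 2 to 1730 and 1004, a pooled fold of 355 (95% exact binomial interval 180 to 824). Reads of gypsy went from 7 and 6 to 823 and 1470, a pooled fold of 183 (107 to 345). The pooled fold was 128 for 412, 183 for Quasimodo (62.4 to 892), 55.5 for mdg1, 20.6 for Tabor, 44.0 for 17.6 (14.7 to 216), and 126 for gypsy5 (22.2 to 5009). No read of gtwin or Stalker4 was counted in EGFP KD, and they were at least 145-fold and 68.6-fold higher in Piwi KD, against a floor of 3 reads over the group. Families that were already abundant differed less, with blood at 3.48-fold, springer at 1.72-fold and copia at 1.35-fold. 

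**Figure D2:**
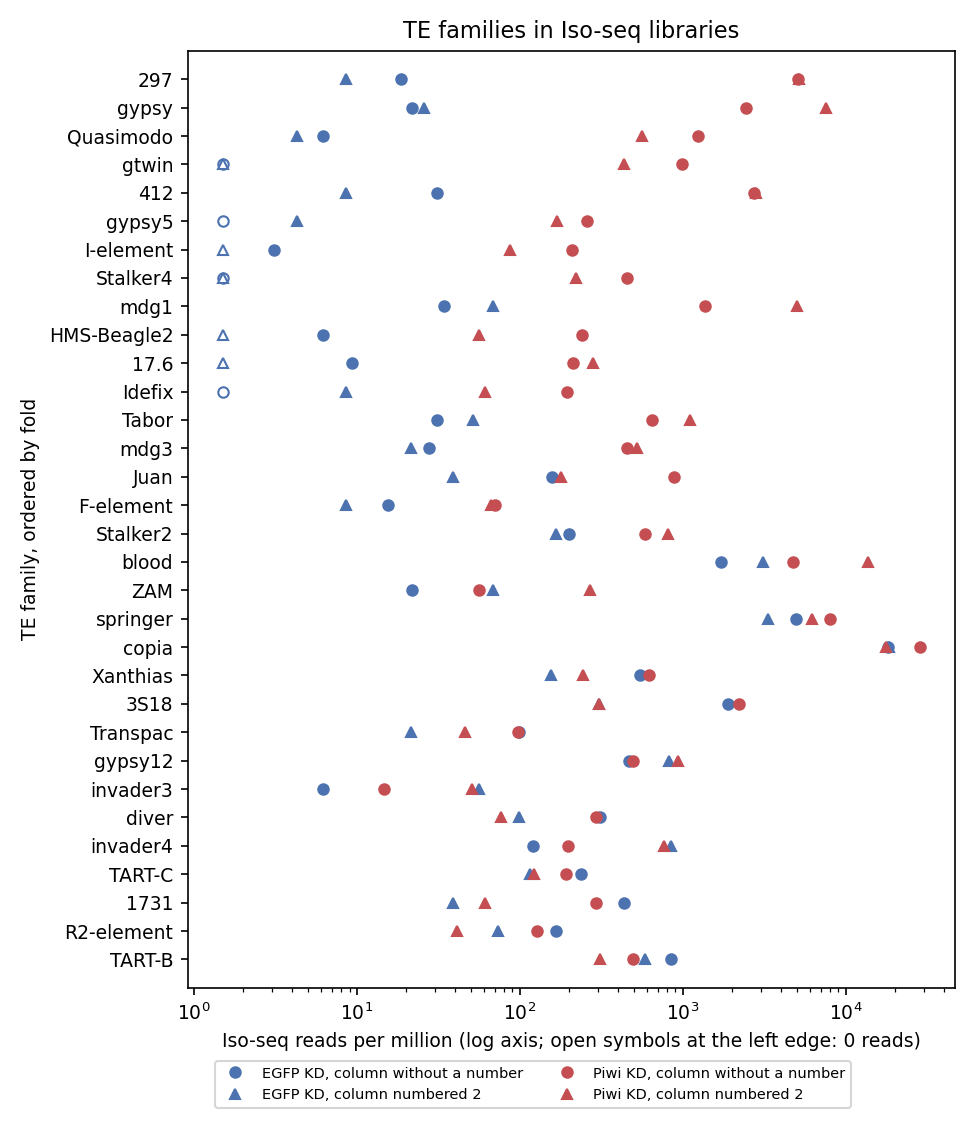
Iso-seq CPM (log axis) of each TE family tested, ordered by fold, with EGFP KD in blue and Piwi KD in red, circles for libraries without a number and triangles for those numbered 2. Open symbols at the left edge stand for 0 reads. Families at the top, such as 297 and gypsy, lie apart by over 100-fold, and TART-B at the foot lies lower in Piwi KD.

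Of 13 families tested that are known mainly from the germline, 4 were higher in both Piwi KD libraries and 1 was lower. The I-element went from 1 read to 88 (91.5-fold, 16.0 to 3654), mdg3 from 14 to 256 (19.0-fold) and Juan from 60 to 335 (5.80-fold). The telomeric element TART-B went from 409 to 228 reads (0.580-fold). The median log2 fold change of the 13 was 0.10. Of 3 families tested on neither list, HMS-Beagle2 alone was higher in both Piwi KD libraries (48.3-fold, 13.0 to 405). Adjusted over the list alone, edgeR called 13 of the 16 follicle-cell families and 2 of the 13 germline families higher. Over all 4409 features edgeR called 0, at an unadjusted p under 0.05 it gave 93 (84 higher, 9 lower), and DESeq2 called 49 of 4152, 11 of them TE families. For 297 the edgeR p was 7.22e-05 and the adjusted p 0.318.

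The 4 Iso-seq libraries fell into 2 sets by the number in their names. Across genes, log-scale levels of the EGFP KD and Piwi KD libraries correlated at 0.885 within the set without a number and 0.863 within the set numbered 2, and at 0.386 to 0.478 for all other pairs. With the set as a term, a fit chosen after the data were seen, edgeR called 267 features, 170 higher and 97 lower. These included 20 TE families higher and 1, TART-B, lower, and 15 of the 16 follicle-cell families and 4 of the 13 germline families were higher. Within each set the share of TE reads was higher in Piwi KD.

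Outside the TE families, the smallest Iso-seq p among features higher in Piwi KD, after 297, gypsy, 412 and Quasimodo, was that of Oat, with 1 and 1 reads in EGFP KD and 98 and 116 in Piwi KD. The lower features with the smallest p, 0 of them past the adjusted threshold, were ImpL2 (43 and 49 reads to 8 and 2), Argk1, the arginine kinase gene (450 and 501 to 142 and 79), piwi, CG31674 and Saf6. Of 41 genes named from CAGE that were tested in Iso-seq, 35 had the same sign. Across 3823 genes measured by both assays the log2 fold changes correlated at a Spearman rho of 0.43 with 64.0% of the same sign, a correlation across genes, which are not independent replicates. Of the 232 genes changed at least 2-fold in CAGE, 85 were also tested in Iso-seq and the others could not be compared. Among these 85, 84 had the same sign in Iso-seq and rho was 0.87.

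CLASH showed what Piwi-bound piRNAs were joined to in untreated cells. TE RNAs made up 45.5 ± 16.3% of chimeras and mRNAs 38.4 ± 9.61%, with rRNA at 6.45 ± 4.00% (SD, n = 5). The libraries formed 2 sets, with a TE share of 64.9% and 61.3% in libraries 1 and 2 and of 31.9%, 32.6% and 36.6% in libraries 3 to 5. Counts per family and per gene cover the 8255 TE chimeras of 1 family and the 5652 mRNA chimeras of 1 gene. The family with most chimeras was gypsy with 1508, followed by 297 with 825, springer with 536, the I-element with 504, blood with 394, copia with 356, 17.6 with 351, Quasimodo with 330, roo with 279 and Doc with 265. Among genes, DIP-alpha, which encodes an immunoglobulin-domain receptor, had 509 chimeras, most often in an intron. The next were dachs with 62, Hsc70-4 with 47, the translational repressor gene pum with 45, kek5 with 41, CG17684 with 39, Imp and SKIP with 38 each, mamo with 35, and lovit and pdm3 with 34 each. These counts are pooled over libraries of unequal size, and library 2 held 28 of the 41 chimeras of kek5. By the mean share of a library's chimeras the order after DIP-alpha (1.89%) and dachs (0.376%) was pum (0.280%), mamo (0.255%) and Hsc70-4 (0.246%), and RpS3 (0.193%), outside the rule for named genes, lay above CG17684, pdm3 and lovit. The first 4 TE families kept their order by that share, and copia (1.66%) lay above blood (1.62%). Of the mRNA chimeras of 1 gene, 48.0 ± 3.83% lay in introns, 17.3 ± 1.83% in 3' UTRs, 16.5 ± 2.57% in coding sequence and 6.61 ± 1.29% in 5' UTRs. A single read supported 87.1% of chimeras.

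Pairing differed between the classes of target. The median hybridization energy was -41.3 ± 3.65 kcal/mol for TE chimeras and -26.1 ± 2.13 kcal/mol for mRNA chimeras (SD, n = 5). The within-library difference was -15.1 ± 1.60 kcal/mol and had this sign in 5 of 5 libraries (exact sign-flip p = 0.0625, two-sided, the smallest that 5 libraries allow, and 0.0729 adjusted over 7 measures). It was -16.8 in libraries 1 and 2 and -13.97 in libraries 3 to 5. TE target parts were longer than mRNA target parts in 5 of 5 libraries, with medians of 45.4 ± 2.61 and 41.2 ± 2.59 nt, and among targets of 40 to 50 nt, a range chosen after the data were seen, the energy difference was -16.03 ± 1.48 kcal/mol (5 libraries, exact p = 0.0625). At least 20 bases were paired in 72.1 ± 13.7% of TE and 29.9 ± 6.29% of mRNA chimeras. Randomly re-paired piRNAs and targets gave medians of -11.3 ± 0.345 and -13.0 ± 0.479 kcal/mol, and 4.74% and 4.57% with at least 20 paired bases. Along the piRNA, TE targets were paired at 84.5%, 85.3% and 83.0% of positions 2 to 8, 9 to 15 and 16 to 22, and mRNA targets at 68.9%, 66.6% and 61.5%. Families and genes spread widely around these medians. Chimeras of gypsy and 297 had median energies of -49.7 and -44.1 kcal/mol, those of springer -33.2 and those of copia -17.4. Among genes, CG17684 and Hsc70-4 lay at -40.8 and -37.9, DIP-alpha at -13.5 and kek5, with a median of 3 paired bases, at -6.19.

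**Figure D3:**
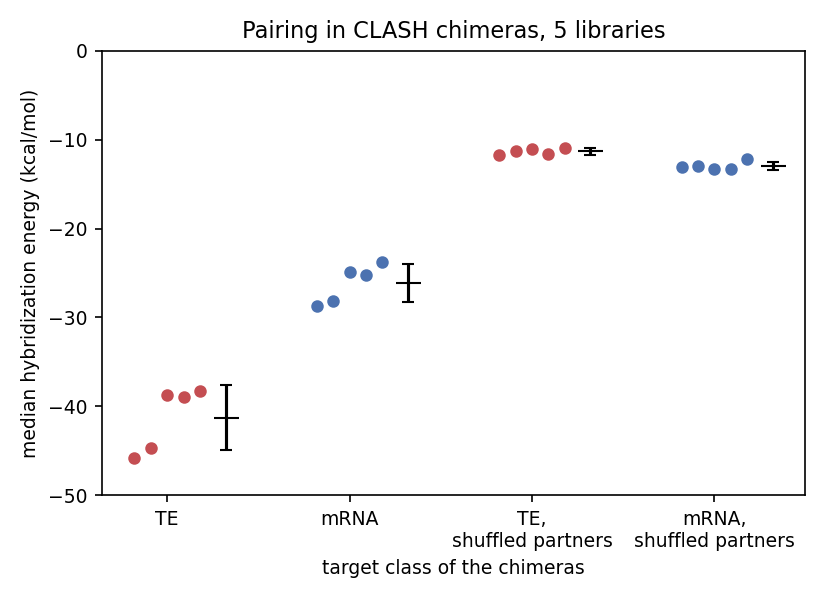
Median hybridization energy (kcal/mol) of TE and mRNA chimeras in CLASH libraries 1 to 5 (points, left to right), beside randomly re-paired partners, with the mean and SD of the 5 libraries as black bars. TE medians center on -41.3 and mRNA medians on -26.1, and both lie below their re-paired partners.

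The median abundance of piRNAs joined to TEs and to mRNAs differed by less than the spread between libraries, while the mean was lower for TEs in each library. The median log2(CPM + 1) was 0.52 ± 0.02 for TE and 0.55 ± 0.04 for mRNA chimeras, with a difference of -0.04 ± 0.05 (lower for TE in 3 of 5 libraries, exact p = 0.25). That difference was 0.02 in libraries 1 and 2 and -0.07 in libraries 3 to 5. These medians sit at the floor of the small RNA table. The CPM used is a mean of 3 small RNA libraries, whose lowest values above 0 were 1.06 to 1.15 CPM. A piRNA at the median was thus listed as 0 in part of them, and the medians could hardly show a difference. The mean log2(CPM + 1) was 0.82 for TE and 0.97 for mRNA chimeras, with a difference of -0.15 ± 0.12 (lower for TE in 5 of 5 libraries, exact p = 0.0625, adjusted 0.0729). The upper end differed as well. piRNAs of at least 10 CPM made up 2.37 ± 0.513% of TE and 5.83 ± 1.98% of mRNA chimeras, lower for TE in 5 of 5 libraries (difference -3.45 ± 1.85 points, exact p = 0.0625, adjusted 0.0729). The piRNA's deposited type was flam, the main somatic piRNA cluster, in 81.3 ± 1.85% of TE and 66.0 ± 4.94% of mRNA chimeras. Types named genic and rmst made up 12.2% and 12.8% of mRNA chimeras and 2.87% and 3.02% of TE chimeras. What rmst stands for was not given in the sources used here, and without that type the difference at 10 CPM was -1.04 ± 0.576 points. The mean log2(CPM + 1) was not recomputed without the rmst type. How much of the lower mean for TEs rests on that type is therefore not known. The pairing values above cover all piRNA types, rmst included.

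Genes whose mRNA was joined to piRNAs went both ways in Piwi KD. Of 53 genes with chimeras in each CLASH library, 36 were measured in CAGE, with 7 higher and 12 lower. Of the genes with most chimeras, SKIP had a CAGE log2 fold change of -0.61 (SE 0.10, edgeR adjusted p = 0.00117), while kek5 at -0.04 and the heat shock cognate gene Hsc70-4 at 0.01 did not pass the test. The median of the 36 was -0.08, at percentile 46.3 of 10000 lists matched on expression. In camera the p was 0.249 (adjusted 0.373 over 9 gene sets) and 0.634 with an estimated correlation. Of the 1021 measured genes with any chimera, 169 were higher and 238 lower, with a median of 0.00 and a mean of -0.04 (camera adjusted p = 0.569).

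TE families with more CLASH chimeras tended to have larger Iso-seq log2 fold changes in Piwi KD. Across 32 families, the number of chimeras and the Iso-seq log2 fold change correlated at a Spearman rho of 0.71 (permutation p = 1e-05, the smallest that 100000 permutations give, adjusted 3e-05 over 3 relations) and a Pearson r of 0.62 (permutation p = 0.00018, adjusted 0.00054). Families such as gypsy and 297 lay at the upper end and TART-B and TART-C at the lower. Without TART-B and TART-C, the farthest from the median, r was 0.58 and rho 0.66. Some follicle-cell families departed from it. Springer (536 chimeras) and blood (394) had log2 fold changes of 0.81 and 1.96, and gtwin (62) and gypsy5 (55) had 10.6 and 6.54. The relation was not tested within the follicle-cell list, so it may rest on the split between lists. The log2 values of gtwin and Stalker4 come from 0 reads in EGFP KD, so their size is uncertain. Families are not independent replicates, and this relation replaced one planned on CAGE after the data were seen.

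The small RNA libraries held mostly flam piRNAs with a 5' T. The flam type made up 77.3 ± 9.60% of listed CPM, and 90.0 ± 1.64% of listed CPM began with T (SD, n = 3). The most abundant sequence was TGCTTGGACTACATATGGTTGAGGGTTGTA, typed rmst, at 1068, 7341 and 9665 CPM in libraries 1, 2 and 3. It matches the 2S rRNA of Drosophila as known from textbooks, and the next 4 sequences by mean CPM were shortened or single-base forms of it. The 100 most abundant sequences held 2.61%, 8.21% and 11.3% of listed CPM. Without the rmst type they held 2.00%, 3.67% and 4.06%. Library 1 stood apart from the others. Over 23763 sequences of at least 1 CPM in each library, rho was 0.34 between libraries 1 and 2, 0.29 between 1 and 3, and 0.78 between 2 and 3. Over all 135957 sequences above 0 in any library, many of them listed as 0 in another, rho was -0.005, -0.084 and 0.549.

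Full-length fusion isoforms joined TE sequence to genes in most cases. Of 1544 fusions, 1020 joined a TE to an annotated gene and 409 joined a TE to an unannotated locus. The TE springer occurred in 687 fusions with 254 genes, 446 of them starting at position 153 of the element. The TE gypsy occurred in 289 fusions with 83 genes, 138 of them starting at position 238, and copia occurred in 143. Relative to the family's Iso-seq reads this was 109 fusions per 1000 reads for springer, 125 for gypsy and 6.14 for copia. Fusions are distinct isoforms and the reads were counted apart from them, so this is not the share of reads that were fused. For roo and jockey, with few reads, the ratio was 1067 and 1222 per 1000 reads. The fusion table carried no read counts per library, so fusions could not be compared between knockdowns.

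Genes fused to gypsy were mostly higher in Piwi KD by CAGE, a comparison chosen after the data were seen. Of 40 such genes measured, 24 rose and 6 fell, with a median log2 fold change of 0.43. In camera from limma the set's adjusted p was 0.000129 over 9 gene sets. With an estimated correlation the p was 0.0616 and the adjusted p 0.277. That median lay above each of the 10000 matched lists. Examples, chosen after their values were seen, were KCNQ at 2.12, CG4928 at 2.40, MESK2 at 1.29 and the checkpoint kinase gene grp at 1.20, while CG32521 had -1.53. Of 166 genes fused to springer, 33 were higher and 61 lower with a median of -0.12 (camera adjusted p = 0.0502, 0.0448 with the replicate number as a block, and p = 0.413 with an estimated correlation). Of 18 fused to copia, 1 was higher and 10 lower with a median of -0.29 (camera adjusted p = 0.00956, and p = 0.161 with an estimated correlation). The medians of the springer and copia sets lay below each of their 10000 matched lists, so an extreme placement was not particular to gypsy.

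**Figure D4:**
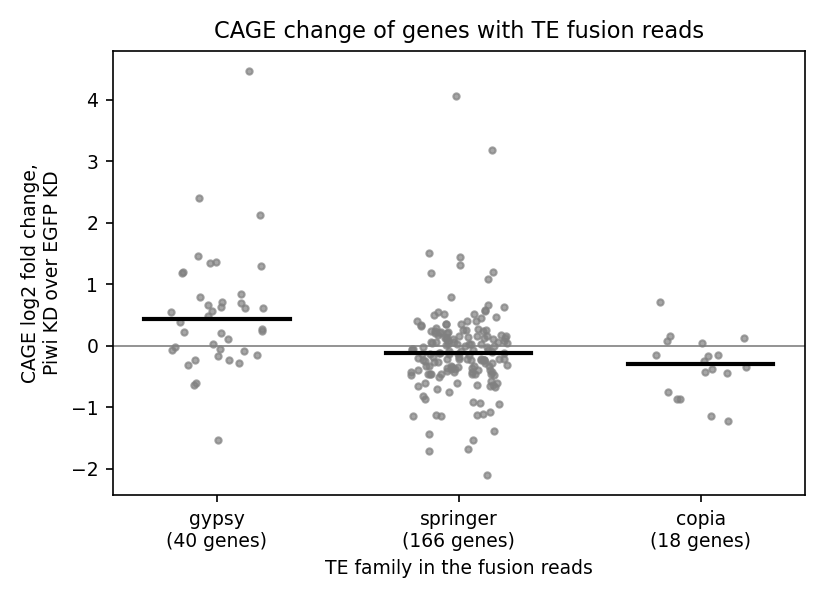
CAGE log2 fold change (Piwi KD over EGFP KD) of single genes found in fusion isoforms with gypsy, springer or copia (points), with the median of each set as a black line. The medians are 0.43, -0.12 and -0.29.

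The annotated haplotypes of flam, on the X chromosome, were dense in TE sequence of 1 orientation. Haplotype 1 held 562 TE entries of 51 families covering 250259 bp, or 64.8% of the annotated span, and haplotype 2 held 942 entries of 60 families covering 518574 bp, or 72.04%. The minus strand held 82.8% and 80.1% of those bases. Quasimodo covered most bases in haplotype 1 at 48522, followed by gypsy4, gypsy, jockey2 and jockey, and in haplotype 2 the order was Quasimodo, gypsy4, gypsy, gypsy6 and springer. All 51 families of haplotype 1 were also in haplotype 2, which held 9 more. The 20A haplotypes each held 40 entries of 12 families, equal in position, family and strand, with roo, 297, 17.6, Stalker4 and mdg1 covering most bases. These are single assemblies without replicates.

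The positions of capped ends were largely shared. Of 8709 tag clusters listed for EGFP KD, 8705 (99.95%, 95% Wilson interval 99.9 to 99.98) overlapped a cluster of Piwi KD on the same strand, and of 8733 listed for Piwi KD, 8703 (99.7%, 99.5 to 99.8) overlapped one of EGFP KD. The lists are 1 per condition and carry no levels.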

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

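The tests of scaling for the ribosomal protein genes and of other splits of the libraries were chosen after the results were seen, as were the sets of genes fused to a TE. Of 32 measures over the 5 CLASH libraries, 1 had a library far from the others. The median energy of randomly re-paired mRNA partners was -12.2 kcal/mol in library 5, against -13.3 to -12.99 in the others, and chance marks about 1 in 20 such groups.

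Genes found in fusion isoforms with gypsy were mostly higher in Piwi KD by CAGE, with a median log2 fold change of 0.43. Template switching between abundant RNAs predicts partners at or above percentile 75 of CAGE level, and for the 60 of 83 partners also read as single genes in Iso-seq the median percentile was 38.2, under the bound of 50 set beforehand. Fewer of the 60 had a CAGE cluster (65.0%) than of all genes read in Iso-seq (81.6%), which goes against abundant partners. Of the 83, 43 had none, but partners naming several genes could not be matched to CAGE features by name. That count is therefore no measure of abundance. The pattern covers only genes with a cluster. Among the 39 of the 60 with one, the median was 53.8 (95% order-statistic interval 41.9 to 75.2, computed after the result was seen). That interval reaches both bounds, so template switching stays open. Open too is an easier detection of fusions on genes that are abundant in Piwi KD, because genes fused to other families at least 10-fold higher in Iso-seq also lay above matched lists, with a median of 0.15 against an upper limit of 0.13. A candidate biological explanation, which was not tested, is that derepressed insertions drive neighbouring genes. It would also raise genes fused to those other families, so that comparison cannot tell it from easier detection.

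Among mRNA chimeras the share of piRNAs of at least 10 CPM was higher than among TE chimeras in 5 of 5 libraries, by 3.45 points on average (TE minus mRNA, -3.45). Sequences of the rmst type, which include forms of 2S rRNA, accounted for part of it, since without them the difference was -1.04 ± 0.576 points, and the same sign in 5 of 5 libraries argues against them as the whole cause. The choice of small RNA library stays open. With the CPM of library 1 alone the mean was -3.34 ± 2.74 points, but 1 of 5 libraries was not below 0. No biological explanation was tested.

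Ribosomal protein genes were lower in Piwi KD, with a median of -0.35. Scaling stays open for the size of the fall, since library totals gave a median of -0.17, while the distance to the median of all genes was -0.37 with either scaling, which shifts all genes alike. A trend with transcript abundance may contribute and stays open. Other genes matched on level had a median of -0.17, a difference of 0.19 from the list, and the match was incomplete, at a median log2 CPM of 10.6 against 12.0. An effect of Piwi depletion on these genes stays open as well.

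For the CAGE comparison as a whole, the real split of the 6 libraries gave 1974 changed genes and the highest of the other splits gave 0. Only 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Of the other splits, 3 part as many replicate numbers as the real one does, and these gave 0 genes.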

How the results depend on the processing

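Library totals in place of TMM factors, the Iso-seq library set as a term and the CLASH library subsets were chosen after the data were seen. RLE factors, DESeq2, clusters in place of genes and no count filter kept the count of changed CAGE genes within 1.5 times of 1974. Library totals gave 3185 genes (2619 higher, 566 lower), and a minimum of 2-fold gave 232 (81 higher, 151 lower), by construction. Leaving out each library in turn gave 1306 to 2286 genes (505 to 1032 higher, 801 to 1254 lower), the lowest without Piwi KD replicate 2. With the replicate number as a block, CAGE gave 2844 genes, 1344 of them higher, piwi at -2.22 and 1 of the 18 lists, and the block brought the set of genes fused to springer past the threshold (adjusted p = 0.0448 over 9 sets) and changed no other call. With an estimated correlation 0 lists passed. Of 72 named genes, 57 kept their direction and side of the threshold under every alternative of scaling, test, count filter, block and left-out library, and 0 reversed. Clusters in place of genes and the minimum fold are not part of that count. CycB3, Su(var)2-10 and stau lost their call without any 1 library other than EGFP KD replicate 1. Leaving out EGFP KD replicate 2 also ended the calls of Dcr-1, Mef2, cact, squ, loqs and Gadd45, EGFP KD replicate 3 those of Dcr-1, Mef2, cact and Dcp-1, Piwi KD replicate 1 those of Mef2, cact, Dcp-1, loqs and Gadd45, Piwi KD replicate 2 those of Dcr-1, Mef2, Dcp-1, Cdk4 and Hsp70Ab, and Piwi KD replicate 3 those of Dcr-1 and Gadd45. DESeq2 ended those of CycB3, Su(var)2-10, Dcr-1, Gadd45, loqs and Hsp70Ab, and library totals those of CycE, Dcp-1, Dcr-2, Gadd45, RnrS and cact. The cause of these shifts was not tested.

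Iso-seq gave 0 features with edgeR (93 at an unadjusted p under 0.05), 49 with DESeq2, 30 without a count filter, 267 with the library set as a term and 4 to 16 with each library left out, where the lone library of a group is assumed to vary like the others. The library set term stands for the block by replicate number chosen beforehand, since 2 of the 4 columns carry no number. The median of genes with chimeras in at least 1 library was 0.00409, opposite in sign to that of genes in all 5, and the abundance difference was 0.0162 in CLASH libraries 1 and 2 alone. TE copies of at least 500 bp numbered 147 and 282 in the flam haplotypes and 19 and 19 in 20A, with 83.7%, 79.4%, 79.2% and 79.2% of bases on the minus strand. With reciprocal overlap, 99.8% of EGFP KD and 99.5% of Piwi KD tag clusters were shared.

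Chosen before the data were examined but not run were single CAGE runs, scaling without TE features, TE rows and a TE count filter in CAGE, sense TE reads alone, pseudocounts, a cluster score minimum (scores are all 0) and a read minimum for fusions (columns are empty).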

Other observations

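The relations of TE families to energy and flam bases were chosen after the data were seen, as were the examples named below. Iso-seq reads in Piwi KD also came from loci without an annotated gene. Whether these loci hold TE insertions, or share reads with the TE families, was not tested. They are therefore not shown to be separate from the TE families. Of the unannotated loci with an unadjusted edgeR p under 0.05, all 60 were higher in Piwi KD, though 0 features passed the adjusted threshold. The locus at chromosome 2R, 5049409 to 5056445, minus strand, had 0 and 2 reads in EGFP KD and 500 and 944 in Piwi KD, a pooled fold of 751 (207 to 6204). At chromosome 2L, 20190807 to 20197776, minus strand, 0 reads became 202, at least 70.0-fold higher against a floor of 3 reads over the group. A locus at chromosome 2R, 24728253 to 24729835, plus strand, went from 3 reads to 273 (94.6-fold, 32.0 to 462).

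Capped ends within a gene did not always go the same way. Of 1244 genes with several tag clusters tested, 61 had clusters changed in both directions in CAGE. In lig, the cluster at chromosome 2R, 8068288 to 8068308, rose by 3.22 on the log2 scale and that at 8068042 to 8068046 had a log2 fold change of -0.88. In Saf6, a cluster at chromosome 2L, 815672 to 815861, had -2.52 and its neighbour at 815901 to 815945 had 0.70. ITP had -1.63 at chromosome 2R, 24539938 to 24539942, and 1.33 at 24543694 to 24543698.

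Across TE families, 2 hypotheses on the extent of the Iso-seq change were tested, among 3 relations. Families with more bases in the flam haplotypes may be those more repressed by Piwi. Their bases and log2 fold changes correlated at a rho of 0.63 (permutation p = 0.0002, adjusted 0.0003) and an r of 0.51 (permutation p = 0.00318, adjusted 0.00477) over 32 families, and at a rho of 0.58 and an r of 0.47 without 3S18 and gypsy12. These 2 tie with other families at 0 flam bases, so their choice was arbitrary. Among follicle-cell families, springer (mean of 18891.5 bases) had a log2 fold change of 0.81 and 297 (6133.5) had 8.51. The relation was not tested within that list, so presence in flam cannot be told from the number of bases. The second hypothesis was that families whose chimeras pair more strongly change more. Over 25 families of at least 10 chimeras, rho was -0.31 (permutation p = 0.134) and r was -0.50 (permutation p = 0.00752), and without copia and gypsy12 r was -0.37 and rho -0.14, so this stays open. Families share sequence and are not independent replicates.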
